A study of Mus musculus with 10 samples.

How the data were processed

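The analysis used the table of gene values that the authors deposited, with 21101 genes and 10 libraries, and no sequence reads were analysed here. The values were log2 values as deposited by the authors, who, per the submitters' processing notes, aligned reads of total RNA libraries with STAR to mm10. Versions, the gene annotation and the tool that made the expression values are not given in the sources used here. From the values, all 10 libraries hold the same sorted set, so they were quantile-normalised before deposit. The lowest value is -8, with 1213 genes at it in each library, and the values back-transformed from log2 add up to 997524 per library, so they were read as log2 of TPM. The design had assumed linear TPM, so the values were back-transformed from log2 and the planned test was kept. In each library 14232 genes had at least 1 TPM. Quantile normalisation fixes the distribution in every library, so a change in total expression cannot be seen, and normalising again moved nothing.

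Values were back-transformed, and log2(TPM + 1) was fitted with limma 3.58.1 (R 4.3.3) with a mean-variance trend. Fold changes are on that scale and understate changes of genes with low levels. Genes with at least 1 TPM in at least 2 of the 10 libraries were tested, 15660 in all. The fit held 4 group means over all 10 libraries, which left 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, with a threshold of 0.05. The 5 comparisons were Atrx-deleted against control lines in each medium, differentiation against proliferation medium in the control and in the Atrx-deleted lines, and the difference of these responses (interaction). One estimate of spread per gene was shared by all groups, although the median SD over genes was 0.148 and 0.141 in the control groups and 0.264 and 0.353 in the Atrx-deleted groups. A shared estimate can be too strict for groups of smaller spread and too liberal for groups of larger spread, which was not tested with equal spreads.

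Genes were named by a rule: adjusted p below 0.05, log2 change of at least 1, a mean of at least 5 TPM in the higher group and no overlap between the libraries of the groups. Of these the 10 largest rises and the 10 largest falls were named, and symbols of clone type were counted but passed over. For each list, up to 3 members that rose and 3 that fell past the test per gene were added, those with the largest change. Atrx, Daxx, Trp53, Idh1, H3f3a, H3f3b, Sox2, Nes, Tubb3, Dcx, Map2, Gfap, Olig2 and Mki67 were always given. Where no gene passed, the 5 genes of smallest p were to be named, which was not needed. Some genes that the rule names are not reported here. These rules, the comparisons, the filter and the lists were set before the data were examined.

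Gene lists were written from general knowledge. Of 32 fixed lists, 29 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry, a rotation test, were run beside it. Of 145 list tests 27 passed with the preset correlation, 0 with the estimated one and 4 with fry. The list of mitochondrially encoded genes had no member in the table. A list of genes linked to ATRX in earlier work had 4 tested members, of which Csf2ra passed, and a list of line sex genes had 1. A correlation preset at 0.01 takes list members as nearly independent, so its p-values are a ranking more than an error rate.

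In simulated data with the gene means and the spread per group of these libraries, changes of log2 1, 2 and 3 were recovered for 19.4%, 56.9% and 85.2% of changed genes in proliferation medium, and for 29.2%, 60% and 71.4% in differentiation medium. The values were 18.3%, 58.1% and 75.8% for the medium in control lines, 40.7%, 74.6% and 95.9% in Atrx-deleted lines, and 4.35%, 40% and 63.4% for the interaction. False calls numbered 2, 7, 0, 24 and 2 in the same order. Simulated values were drawn independently for each gene and library, with a pooled SD per gene scaled by group. Correlation between genes, lasting differences between lines and a wrong label were not simulated, so recovery and false calls in these libraries can differ.

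The same line labels appear in both media, so a fit with the cell line as a block was run for the comparisons of media. Pairs were checked by the correlation of deviations from the group mean between the libraries of a line: r was 0.159 for mA16d#4, 0.404 for mA19d#4, -0.194 for the label mA19d#7 and 0.0624 for the control lines. Alternatives tried were pseudocounts, filters, limma without trend or with robust estimation, the compared groups fitted alone, the line as a fixed or random block, median-of-ratios factors, and each library and line left out in turn. Testing the deposited log2 values directly, a weight per group, and the block without mA19d#7 were added after seeing the data. Positions are from GENCODE M21 (GRCm38), in which 20765 of 21101 symbols (98.4%) were found. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and figures.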

Results

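Gene expression was measured by RNA sequencing in 10 libraries of mouse neural stem cells that lacked p53 and carried a transduced mutant isocitrate dehydrogenase, IDH1(R132H). Atrx encodes a chromatin remodeller that, with Daxx, deposits the histone variant H3.3 at repetitive and heterochromatic DNA. The libraries came from 2 control lines (Control NSC#1 and Control NSC#2) and 3 Atrx-deleted lines (mA16d#4, mA19d#4 and mA19d#7). Each line was sampled once in proliferation medium with EGF and bFGF at 20 ng/ml, and once after 8 days in differentiation medium, which contained B27 and no growth factors. The 4 groups therefore held 2, 2, 3 and 3 libraries, and the title of the series concerns the part Atrx plays in neuronal differentiation. The deposited table gives 1 value per gene and library, and every library holds the same set of values, so sequencing depth is unknown and no counting error can be given. Of 21101 genes, 15660 were tested. The p-values per gene measure the spread between these lines, each of which was sequenced once per medium, while list tests at a preset correlation take genes as the units. No label says how the lines were derived from each other, and the tests over lines take them as independent. The deposited sample codes share a number prefix among all control libraries and a different prefix among all Atrx-deleted libraries. What the prefix stands for is not given. Any difference in handling that followed it could not be told apart from a difference between Atrx-deleted and control lines.

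The control libraries of a medium resembled each other more closely than the Atrx-deleted libraries did. Spearman's rho across genes was 0.983 between the control libraries in proliferation medium and 0.978 in differentiation medium. It ranged from 0.953 to 0.976 among the Atrx-deleted lines in proliferation medium and from 0.915 to 0.953 in differentiation medium. The median SD over genes of log2(TPM + 1) was 0.148, 0.141, 0.264 and 0.353 for control proliferation, control differentiation, Atrx-deleted proliferation and Atrx-deleted differentiation. The library labelled mA19d#7 in differentiation medium correlated best with the mA16d#4 library in proliferation medium (rho 0.957). Its value was 0.938 with the mA16d#4 library in differentiation medium, and 0.926 with the proliferation library of its own line label. The first 2 principal components held 27.3% and 22.8% of the variance.

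**Figure D1:**
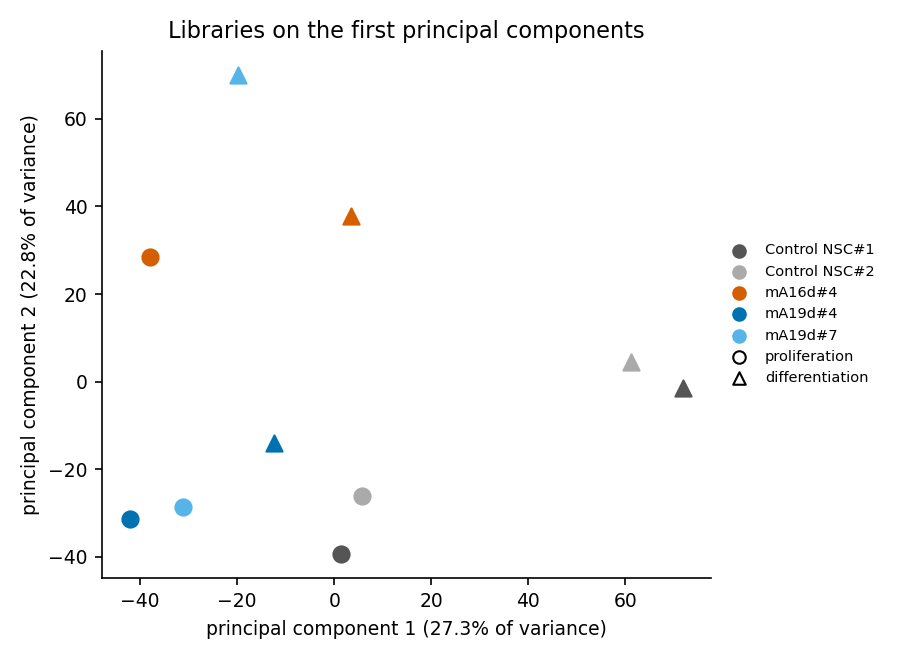
Position of the 10 libraries on the first and second principal components of log2(TPM + 1), in arbitrary units, with colour for the line label, circles for proliferation medium and triangles for differentiation medium. The control libraries in differentiation medium lie at the right (71.9 and 61.1 on the first component), and the library labelled mA19d#7 in differentiation medium lies highest on the second component (70.1).

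Atrx (ENSMUSG00000031229, chromosome X, 105797615 to 105929403, GRCm38) was lower in every Atrx-deleted library than in every control library. In proliferation medium its level was 162.6 TPM and 149.0 TPM in the control lines, and 71.6, 42.8 and 74.0 TPM in mA16d#4, mA19d#4 and mA19d#7. In differentiation medium it was 127.6 and 126.7 TPM in the control lines, against 54.4, 47.2 and 54.0 TPM. The means were 156 ± 9.61 (SD, n = 2) against 62.8 ± 17.4 TPM (SD, n = 3) in proliferation medium, which left 40.3% of the control level. In differentiation medium they were 127 ± 0.623 (SD, n = 2) against 51.9 ± 4.05 TPM (SD, n = 3), which left 40.8%. On the log2 scale the gene fell by 1.34 (SE 0.223, limma adjusted p = 0.039) and by 1.28 (adjusted p = 0.0204). A two-sided exact permutation test over lines gave p = 0.1 in each medium, the smallest value that 2 lines against 3 allow. The adjusted p in proliferation medium passed 0.05 with 2 of the 10 libraries left out in turn, and reached 0.473 without the first control line in that medium. In differentiation medium it rose to 0.192 and 0.127 without the first and the second control library of that medium. The transcript was lowered and not lost, and exons could not be examined separately. Of 20 X-linked genes called in differentiation medium 18 were lower, Atrx among them, and 2 higher. Taf1, Ogt and Hdac8, which start between 101532734 and 102284639, had log2 differences of -1.29, -1.38 and -1.63 there. Over all 537 tested X-linked genes, the median log2 difference lay between -0.367 and 0.0901 in the Atrx-deleted libraries. These values argue against a shift of the whole X chromosome as large as the fall of Atrx. A fall of Atrx alone was not told apart from a difference over the part of the chromosome that holds these genes.

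**Figure D2:**
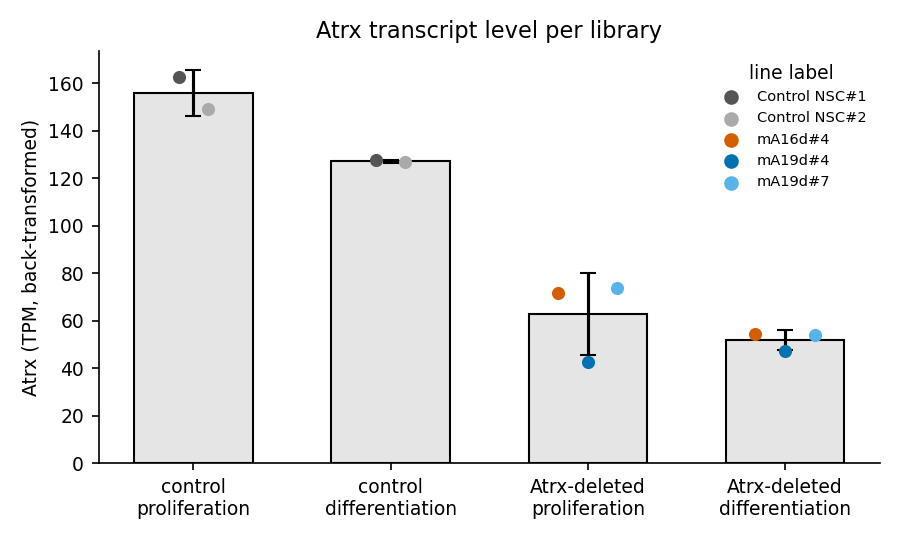
Atrx level (TPM, back-transformed from the deposited log2 values) in the 4 groups, with bars for group means, error bars for 1 SD and points for single libraries coloured by line label. The 6 Atrx-deleted libraries lie between 42.8 and 74.0 TPM and the control libraries between 126.7 and 162.6 TPM.

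In proliferation medium, the genes that passed between Atrx-deleted and control lines had large differences for the most part. Gnao1, the alpha subunit of a neuronal G protein, rose from 2.63 ± 1.94 TPM (SD, n = 2) to 89.6 ± 36.9 TPM (SD, n = 3), and Tbx15, a T-box transcription factor of mesenchymal tissues, rose from 1.23 ± 0.193 to 25.9 ± 6.04 TPM. Csf2ra, a subunit of the receptor for the growth factor GM-CSF, fell from 20.8 ± 7.80 to 0.0555 ± 0.0357 TPM, and Wnt4, a secreted Wnt ligand, fell from 18.9 ± 2.73 to 1.31 ± 0.212 TPM. Cdkn1a, which encodes the cell cycle inhibitor p21 and is a target of p53, rose from 10.2 ± 1.22 to 64.8 ± 4.99 TPM in these p53-null cells. The corresponding log2 differences were 4.68 (SE 0.447, adjusted p = 0.00335) for Gnao1 (chromosome 8, 93809966 to 93969388) and 3.57 (SE 0.274, adjusted p = 0.00162) for Tbx15 (chromosome 3, 99240381 to 99354259). They were -4.32 (SE 0.367, adjusted p = 0.00174) for Csf2ra (chromosome 19, 61223957 to 61228429), -3.10 (SE 0.355, adjusted p = 0.0102) for Wnt4 and 2.55 (SE 0.361, adjusted p = 0.0222) for Cdkn1a.

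The largest rise was that of Ramp1, which modifies the calcitonin receptor-like receptor, from 2.08 ± 2.29 to 176 ± 118 TPM (log2 5.72, SE 0.977, adjusted p = 0.0436). Among the other named genes that rose was Capn6, a calpain family member without protease activity, with a log2 difference of 4.01. Vat1l (3.36), the homeobox gene Hoxa4 (3.34), the zinc finger gene Zfp182 (3.33), the monocarboxylate transporter family gene Slc16a13 (3.32) and Cyp27a1 (3.17), a sterol hydroxylase, also rose. Among the genes that fell were Cldn34c1, a claudin family member (-3.92), Rimbp2, a presynaptic active zone protein (-3.48), and Scarf2, a scavenger receptor (-3.44). Zfp612 (-3.30), Lrrc32 (-3.28), which holds latent TGF-beta at the cell surface, Bex1 (-3.15), Zfp941 (-2.91) and the tetraspanin Cd82 (-2.84) fell as well. Cldn34c1 has close copies among which reads can be shared, so its value is uncertain. Rimbp2 fell from 10.4 ± 2.49 to 0.00846 ± 0.00392 TPM, near the floor of the table.

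In all, 72 genes passed an adjusted p of 0.05 in proliferation medium, 41 higher and 31 lower in the Atrx-deleted lines, and 66 of them differed at least 2-fold. At an unadjusted p under 0.05, 2148 genes passed. In each of the 72 the libraries of both groups did not overlap, which chance gives for 20% of unchanged genes. The 72 were chosen on these same values, so the lack of overlap adds no support. The call count rested on single libraries, being 0 and 3 without the first or second control library of that medium, 22 and 26 without those of differentiation medium, and 29, 6 and 39 without the Atrx-deleted proliferation libraries of mA16d#4, mA19d#4 and mA19d#7. It rose by more than 1.5 times without the differentiation library of mA19d#4, and to 249, with all 72 among them, without the library labelled mA19d#7 in that medium.

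Gene lists fixed before the data were examined described 6 groups that stood apart in proliferation medium. The 19 tested Hox genes, transcription factors of body axis patterning, were all higher in the Atrx-deleted lines (median log2 difference 1.32). Of these, 1 rose over all genes (Hoxa4) and 4 when adjusted over the list alone. The list test (camera with a preset correlation) gave an adjusted p of 5.03e-07, and an adjusted p of 0.631 with an estimated correlation. Interferon response genes lay lower (median -0.65, 18 of 21 negative, adjusted p = 6.73e-05, or 0.631 with an estimated correlation). None of the 21 passed over all genes, and 5 fell when adjusted over the list alone. The 12 genes of MHC class I and antigen presentation lay higher (median 0.80, 11 of 12 positive, adjusted p = 0.00517, or 0.977 with an estimated correlation), with none past the test per gene by either adjustment. The 82 ribosomal protein genes lay higher (median 0.47, adjusted p = 3.97e-12, or 0.631 with an estimated correlation). Of these, 1 rose over all genes, Rpl37a (log2 0.98, adjusted p = 0.0479), against 9 that rose and 1 that fell when adjusted over the list alone. Ribosomal protein genes have many processed copies in the genome, so reads of a member can be shared. The 17 Polycomb complex genes (median 0.25, adjusted p = 0.0186, or 0.631 with an estimated correlation) and the 30 genes of cell cycle and DNA replication (median 0.21, adjusted p = 0.00831, or 0.977 with an estimated correlation) were slightly higher. None of either list passed over all genes, and 2 and 3 rose when adjusted over the list alone. Both list calls were lost without the second control library in proliferation medium (adjusted p = 0.216 and 0.726) and without the mA16d#4 library in that medium (adjusted p = 0.135 for both).

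Lists of neural cell types did not pass in proliferation medium. The median log2 difference was 0.15 for neural stem and progenitor genes, -0.20 for pan-neuronal genes, 0.34 for GABAergic interneuron genes and 0.19 for glutamatergic neuron genes. It was 0.12 for genes of synapses and channels, 0.23 for astrocyte genes and -0.29 for genes of the oligodendrocyte lineage. In the last list 1 gene fell over all genes, Bcas1, a gene of myelinating cells (log2 -2.52, adjusted p = 0.0471), against 2 that rose and 4 that fell when adjusted over the list alone. Markers of cells that a culture of neural stem cells would not be expected to hold gave medians of 0.09 for microglia and macrophages, -0.26 for endothelial and mural cells and 0.03 for ependymal cells and choroid plexus. Signalling lists gave 0.04 for the Notch pathway, 0.11 for Wnt targets, 0.01 for BMP and TGF-beta targets, -0.14 for EGF and FGF signalling targets and -0.19 for p53 targets. The list test gave the opposite sign to the median for EGF and FGF signalling targets and for BMP and TGF-beta targets, and the mean of p53 targets was 0.10. Of the p53 targets, 1 rose over all genes and over the list alone, Cdkn1a. The remaining medians were -0.07 for imprinted genes, 0.13 for H3.3 and heterochromatin machinery, 0.13 for DNA damage and telomere maintenance, -0.07 for cholesterol synthesis and -0.13 for hypoxia and glycolysis. They were -0.07 for unfolded protein and amino acid stress (mean 0.02), 0.33 for extracellular matrix and mesenchymal genes and -0.16 for replication-dependent histones. Adjusted p for the lists that did not pass ranged from 0.135 to 0.971.

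In differentiation medium, several genes of proliferation were higher and several glial genes lower in the Atrx-deleted lines than in the control lines. Of the tested members 14 of 30 cell cycle, 2 of 21 astrocyte and 3 of 16 oligodendrocyte lineage genes passed, and no list passed with an estimated correlation (adjusted p = 0.542, 0.755 and 0.755). The cyclin gene Ccnb1 was at 76.5 ± 35.3 TPM (SD, n = 3) against 14.3 ± 3.17 TPM (SD, n = 2), and Mki67, which marks cycling cells, at 103 ± 54.9 against 23.3 ± 0.320 TPM. Apoe, the main lipid carrier made by astrocytes, was at 1128 ± 280 against 6032 ± 860 TPM, and Slc4a4, an astrocytic bicarbonate transporter, at 124 ± 42.2 against 636 ± 53.8 TPM. The log2 differences were 2.22 for Ccnb1 (SE 0.413, adjusted p = 0.0244), 1.96 for Mki67 (SE 0.376, adjusted p = 0.0271), -2.44 for Apoe (SE 0.516, adjusted p = 0.0372) and -2.40 for Slc4a4 (SE 0.280, adjusted p = 0.00496). The long noncoding RNA Miat (chromosome 5, 112213228 to 112229395) was at 0.131 ± 0.184 against 189 ± 15.6 TPM (log2 -7.41, SE 0.677, adjusted p = 0.00126). The transmembrane gene Tmem132b, on the same chromosome (125531774 to 125792583), was at 0.0777 ± 0.0608 against 96.2 ± 12.1 TPM (log2 -6.49, SE 0.413, adjusted p = 0.000261).

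Mira (log2 4.86), Tbx15 (3.58), Capn6 (3.54) and Hapln4 (3.47) were among the genes with the largest rises in the Atrx-deleted lines over the control lines in differentiation medium. Hapln4 encodes a link protein of the neural extracellular matrix, and Mira had no position in the annotation used here. Shcbp1 (3.36), the homeobox genes Hoxa7 (3.29) and Hoxa10 (3.13), and the mitotic ubiquitin-conjugating enzyme gene Ube2c (3.12) rose as well. After Miat and Tmem132b, the largest falls were those of Csf2ra (-4.46), Bex1 (-4.03), the cytidine deaminase gene Cda (-3.79), Rimbp2 (-3.78) and Scarf2 (-3.77). Svip (-3.75), Pdpn (-3.67), a membrane glycoprotein of glia and mesothelium, and Zfp488 (-3.52), a transcriptional regulator of oligodendrocyte differentiation, fell as well. With each of the 10 libraries left out in turn, 6 of the 53 genes named by rule stayed past 0.05, Csf2ra, Miat, Rimbp2, Tbx15 and Tmem132b among them.

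The comparison in differentiation medium called 452 genes, 243 higher and 209 lower in the Atrx-deleted lines, of which 364 differed at least 2-fold. Without the library labelled mA19d#7 935 genes passed, 416 of the 452 among them. The count was 211 and 212 without the first and second control library in proliferation medium, 11 and 30 without those in differentiation medium, and 261 without the mA19d#4 library in proliferation medium. With the 5 libraries of differentiation medium fitted alone it was 2.

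Genes of cell cycle and DNA replication had the largest median shift of the tested lists in differentiation medium. Of 30 tested, 29 were higher in the Atrx-deleted lines (median log2 difference 1.5), 14 rose over all genes and 25 rose when adjusted over the list alone. The centromeric histone gene Cenpa (2.37), the mitotic activator gene Cdc20 (2.33) and Ccnb1 had the largest differences. The list test gave an adjusted p of 3.44e-18, and an adjusted p of 0.542 with an estimated correlation. Among 20 genes of DNA damage and telomere maintenance (median 0.47, adjusted p = 0.00106, or 0.542 with an estimated correlation), 3 rose over all genes and 6 over the list alone. They were the checkpoint kinase gene Chek1 (1.71), Brca1 (1.5) and the telomere helicase gene Rtel1 (1.25), which lies in a part of chromosome 2 where neighbouring genes were higher too. Of the 22 genes of H3.3 and heterochromatin machinery, a list that did not pass (adjusted p = 0.123), 3 rose over all genes and 4 over the list alone. The 3 were the replication-linked histone chaperone gene Asf1b (1.84), the maintenance methylation factor gene Uhrf1 (1.69) and H3f3a (0.95, adjusted p = 0.0401), which encodes H3.3 and has near-identical copies. EGF and FGF signalling targets lay higher (20 genes, median 0.54, adjusted p = 0.036, or 0.542 with an estimated correlation), with none past over all genes and 2 that rose over the list alone.

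Astrocyte and oligodendrocyte lineage genes lay lower in the Atrx-deleted lines in differentiation medium. Among 21 astrocyte genes (median -0.54, adjusted p = 0.0268, or 0.755 with an estimated correlation) Apoe and Slc4a4 fell over all genes and 6 fell when adjusted over the list alone. Gfap, the astrocyte filament gene, was at 498 ± 792 TPM (SD, n = 3) against 3.11 ± 2.18 TPM (SD, n = 2), a difference that did not pass (log2 4.39, SE 1.79, adjusted p = 0.206). Among 16 oligodendrocyte lineage genes (median -0.74, 13 negative, adjusted p = 0.0146, or 0.755 with an estimated correlation) 3 fell by both adjustments. Among these were the progenitor receptor gene Pdgfra (-2.11) and Bcas1 (-2.03). The astrocyte call was lost without the second control library (adjusted p = 0.0554) or the mA19d#4 library (0.5) of that medium. The oligodendrocyte call was lost without the library labelled mA19d#7 (0.193).

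Neuronal lists did not pass in differentiation medium. Of 24 pan-neuronal genes (median -0.04, adjusted p = 0.5) 1 rose, the neurofilament gene Nefl (1.96), and 2 fell, Rbfox3 (-3.01), which encodes the neuronal marker NeuN, and the granin gene Chgb (-2.89), against 3 and 5 when adjusted over the list alone. Of 10 glutamatergic neuron genes (median -0.03, adjusted p = 0.5) the synaptic kinase gene Camk2a fell (-3.27) by both adjustments. Interferon response genes, which lay lower in proliferation medium, had a median of 0.31 (adjusted p = 0.344). Genes of GABAergic interneurons (median 0.68, adjusted p = 0.5) and of synapses and channels (median 0.02, mean -0.14, adjusted p = 0.844) held no gene past the test per gene. Among neural stem and progenitor genes (median 0.10, adjusted p = 0.5) the matrix gene Tnc rose (3.09, adjusted p = 0.0177) by both adjustments.

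Further lists stood higher in the Atrx-deleted lines in differentiation medium. All 19 Hox genes were again positive (median 1.28, adjusted p = 3.23e-06, or 0.542 with an estimated correlation), 5 rose over all genes and 7 over the list alone, and Hoxa7, Hoxa10 and Hoxa3 (2.62) had the largest differences. The annotated span of Hoxa3 covers other Hoxa genes, so its reads can overlap theirs. Ribosomal protein genes (82, median 0.35, adjusted p = 2.79e-06, or 0.755 with an estimated correlation) included 5 that rose over all genes, among them Rpsa (1.46) and Rplp0 (1.29). Adjusted over the list alone, 11 rose and 2 fell. Genes of MHC class I and antigen presentation (12, median 0.98, adjusted p = 0.00149, or 0.755 with an estimated correlation) included 1 that rose over all genes, the immunoproteasome gene Psmb8 (2.30), and 6 over the list alone. That list call was lost without the library labelled mA19d#7 (adjusted p = 0.0868). Polycomb complex genes (17, median 0.28, adjusted p = 0.0268, or 0.542 with an estimated correlation) had none past over all genes and 5 that rose over the list alone. The Polycomb call was lost without the second control library (0.0554) or the mA19d#4 library (0.097) of that medium, and that of EGF and FGF signalling targets without the first control library (0.117) or the mA19d#4 library (0.097). Members of other lists that passed the test per gene were Notum (2.33), a Wnt target that inactivates Wnt ligands, Gtse1 (2.03) and Cdkn1a (1.63) among p53 targets, the imprinted receptor gene Igf2r (1.33), the matricellular gene Ctgf (-2.76) among BMP and TGF-beta targets, and the glucose transporter gene Slc2a1 (-1.33) among hypoxia and glycolysis genes.

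Genes that differed between Atrx-deleted and control lines overlapped between the media. Of 41 genes higher in proliferation medium and 243 higher in differentiation medium, 18 were shared, where independent lists would share 0.636. Of 31 and 209 lower genes 18 were shared, where independent lists would share 0.414, and no gene was called in opposite directions. The groups compared held no common library but the same 5 lines, so lasting differences between lines enter both. The estimate of spread per gene, from all 10 libraries, also served both, so the calls are not independent between media. Of the 72 genes called in proliferation medium, 68 (94.4%) had the same direction in differentiation medium, with a median size of 1.28 against 2.03 in the medium they were chosen in.

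Genes near the distal end of chromosome 2 were higher in all 6 Atrx-deleted libraries. Over the 66 tested genes in the last 5 Mb, the median log2 difference from the control lines in the same medium ranged from 0.66 to 0.90 between libraries. A least-squares step in the mean of the 6 libraries placed the change at Ube2v1 (chromosome 2, start 167607638), with a median of 0.72 over the 116 genes from there to the end and -0.02 over the 1106 genes before it. Fitted per library, the step started between 167062934 and 167607638 in 5 libraries and at 179414936 in the mA19d#4 library in differentiation medium. That segment held 8 of the 72 genes called in proliferation medium (11.1%, 7 higher) and 18 of the 452 called in differentiation medium (3.98%, 16 higher). Of the named genes in it, Rtel1 was higher in differentiation medium, and Bcas1 was lower in both media, against the direction of the segment. Of the 30 genes of cell cycle and DNA replication 1 lay in it, and the median difference in differentiation medium was 1.46 without that gene.

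**Figure D3:**
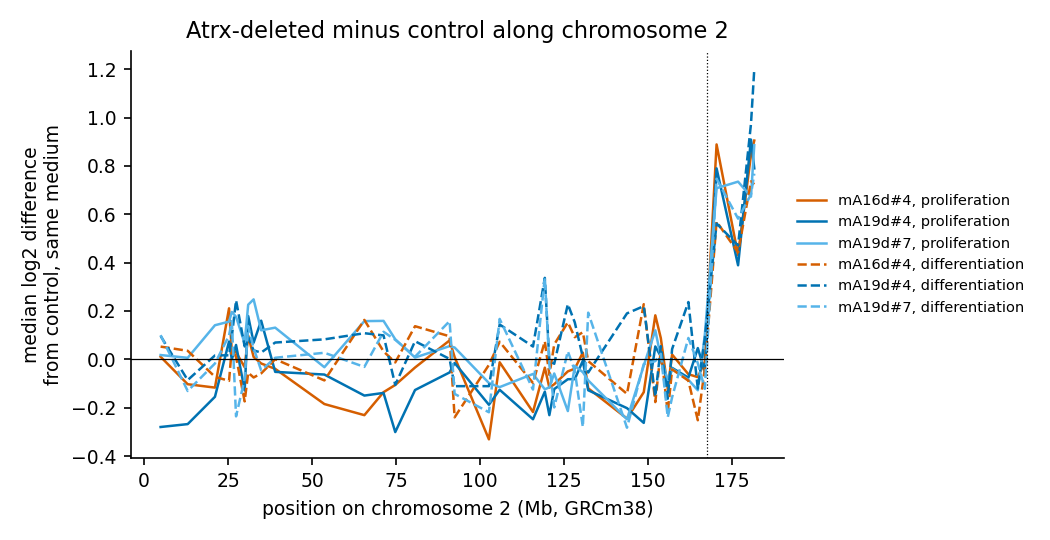
Median log2 difference of each Atrx-deleted library from the mean of the control libraries in the same medium, over successive groups of about 30 genes along chromosome 2 (Mb, GRCm38), with colour for the line label and dashes for differentiation medium. The 6 lines stay near 0 up to the dotted step at Ube2v1 and lie above it from there to the end of the chromosome.

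In the control lines, several genes of proliferation fell and several astrocyte genes rose in differentiation medium. Of the tested members of these lists 15 of 30 and 6 of 21 passed, and neither list passed with an estimated correlation (adjusted p = 0.619 and 0.543). Mki67 fell from 239 ± 94.9 to 23.3 ± 0.320 TPM (SD, n = 2 each), and Apoe rose from 556 ± 279 to 6032 ± 860 TPM. Slc1a2, the main astrocytic glutamate transporter, rose from 53.2 ± 17.7 to 396 ± 34.9 TPM, and Nes, the stem cell filament gene, fell from 587 ± 77.8 to 264 ± 27.2 TPM. Elavl3, an RNA-binding protein gene of neurons, rose from 1.68 ± 1.06 to 16.7 ± 4.77 TPM. The log2 changes were -3.24 for Mki67 (SE 0.412, adjusted p = 0.00532), 3.53 for Apoe (SE 0.566, adjusted p = 0.0108), 2.91 for Slc1a2 (SE 0.513, adjusted p = 0.015), -1.15 for Nes (SE 0.236, adjusted p = 0.0262) and 2.76 for Elavl3 (SE 0.619, adjusted p = 0.0359).

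The largest rise was that of the zinc transporter gene Slc39a12, from 0.549 ± 0.707 to 80.2 ± 3.89 TPM (log2 5.79, SE 0.681, adjusted p = 0.00532). Tmem132b (5.42), Ctgf (4.63), Ucma (4.51), the stearoyl-CoA desaturase gene Scd4 (4.37) and Psd2 (4.32) came next. The matrix proteoglycan gene Fmod (4.10), Miat (4.05), the adrenergic receptor gene Adra2a (4.01) and the phospholipid scramblase gene Plscr2 (3.99) also rose. Among genes that fell, Cd93 (-3.97), Gcnt4 (-3.79), the interferon-inducible GTPase gene Gbp9 (-3.71), a member of a family of close copies, and the Nogo receptor family gene Rtn4rl1 (-3.61) led. Further falls were those of Ube2c (-3.53), Fam64a (-3.49), Psrc1 (-3.45), Hrc (-3.45) and the mitotic phosphatase gene Cdc25c (-3.44). With each of the 10 libraries left out in turn, 2 of the 51 genes named by rule stayed past 0.05, Tmem132b among them.

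In the control lines 706 genes passed, 305 higher and 401 lower in differentiation medium, of which 598 changed at least 2-fold. The count was 1447, with all 706 among them, without the library labelled mA19d#7, 6 and 153 without the first and second control library in proliferation medium, and 10 and 15 without those in differentiation medium. With the 4 control libraries fitted alone it was 2080.

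Of 30 genes of cell cycle and DNA replication, 28 were lower in the control lines in differentiation medium (median -1.36), 15 fell over all genes and 20 when adjusted over the list alone. Mki67, Cenpa (-3.08) and Ccnb1 (-2.95) fell most, and the list test gave an adjusted p of 2.28e-14, or 0.619 with an estimated correlation. Of 21 astrocyte genes 18 were higher (median 1.17, adjusted p = 2.56e-06, or 0.543 with an estimated correlation), 6 rose over all genes and 9 over the list alone, led by Apoe, Slc1a2 and Slc4a4 (2.82). Interferon response genes lay lower (21, median -1.12, adjusted p = 5.49e-05, or 0.638 with an estimated correlation). Of these, 4 fell over all genes, among them Rsad2 (-2.37), Rtp4 (-2.17) and Oasl1 (-1.96), and 7 over the list alone. EGF and FGF signalling targets lay lower (20, median -0.63, adjusted p = 0.00412, or 0.543 with an estimated correlation), and Spry4 (-1.55), a feedback inhibitor of receptor tyrosine kinases, and the ETS factor gene Etv5 (-1.46) fell over all genes, with 3 over the list alone. Ribosomal protein genes lay lower (82, median -0.54, adjusted p = 1.25e-08, or 0.771 with an estimated correlation), with 1 that fell over all genes, Rplp0 (-1.24), and none over the list alone. A test of joint direction (fry) gave an adjusted p of 0.0423 for each of the first 4 of these lists and 0.126 for ribosomal protein genes.

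Neuronal lists did not pass in the control lines. Of 24 pan-neuronal genes (median 0.27, adjusted p = 0.206) Elavl3 and Mapt (1.04), which encodes the microtubule protein tau, rose over all genes, and 3 over the list alone. Of 16 genes of synapses and channels (median 0.30, adjusted p = 0.222) the neurexin gene Nrxn3 rose (3.31), and 3 over the list alone. GABAergic interneuron genes (median -0.04, mean 0.05, adjusted p = 0.956), glutamatergic neuron genes (median 0.28, adjusted p = 0.558) and oligodendrocyte lineage genes (median 0.26, adjusted p = 0.682) held none past by either adjustment. Of 22 neural stem and progenitor genes (median -0.19, adjusted p = 0.109) Tnc (-3.34), the chromatin gene Hmga2 (-2.58) and Nes fell, and 4 over the list alone. Members of other lists that passed were Gtse1 (-2.77), Asf1b (-1.93), Brca1 (-1.69), Igf2r (-1.60), the chaperone cofactor gene Sdf2l1 (-1.17), Hoxa5 (-1.15) and Jarid2 (-0.72), a Polycomb cofactor. Slc2a1 (1.65), the Polycomb gene Pcgf2 (1.34), the stress transcription factor gene Atf4 (1.02), the histone chaperone gene Asf1a (1.00), the serine synthesis gene Phgdh (0.96) and the sterol desaturase gene Sc5d (0.88) rose.

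In the Atrx-deleted lines, 13 genes passed for differentiation medium, 2 higher and 11 lower, and 12 were named by rule. The adhesion molecule genes Cadm2 and Negr1 rose, from 4.61 ± 0.896 to 23.7 ± 6.87 TPM and from 3.43 ± 1.23 to 14.8 ± 2.76 TPM (SD, n = 3 each). Tle6 and Tle2, neighbouring genes of the Groucho family of corepressors, fell from 118 ± 4.97 to 37.1 ± 5.92 and from 74.8 ± 5.75 to 28.8 ± 5.94 TPM. The log2 changes were 2.11 for Cadm2 (SE 0.282, adjusted p = 0.0361), 1.86 for Negr1 (SE 0.271, adjusted p = 0.0488), -1.66 for Tle6 (SE 0.150, adjusted p = 0.00775) and -1.37 for Tle2 (SE 0.179, adjusted p = 0.0349). Myadm (-2.78), Acy3 (-2.29), the collagen gene Col28a1 (-2.28), the phosphatase gene Ptp4a3 (-2.24), Rhbdl3 (-1.76), the diacylglycerol kinase gene Dgkz (-1.52), the oestrogen-responsive receptor gene Gper1 (-1.5) and Rpl12 (-1.45) fell. At an unadjusted p under 0.05, 2319 genes passed.

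The count of 13 was 348, with the 13 among them, without the library labelled mA19d#7, and 53 and 2 without the mA19d#4 and mA16d#4 libraries in differentiation medium. It was 1 without any of the 4 control libraries and 0 without the mA19d#4 or mA19d#7 library in proliferation medium. With the cell line as a block it was 6, 5 of them among the 13, and with the 6 Atrx-deleted libraries fitted alone it was 0. With the block and without the line labelled mA19d#7 it was 335. On simulated data this comparison made 24 false calls, more than any of the other 4.

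Ribosomal protein genes lay lower in differentiation medium in the Atrx-deleted lines as well (82, median -0.51, adjusted p = 1.41e-20, or 0.811 with an estimated correlation), with Rpl12 past over all genes and 28 that fell over the list alone. Neural stem and progenitor genes lay lower (22, median -0.50, adjusted p = 0.00163, or 0.811 with an estimated correlation), astrocyte genes higher (21, median 0.68, adjusted p = 0.0243, or 0.870 with an estimated correlation) and cell cycle genes lower (30, median -0.38, adjusted p = 0.00168, or 0.966 with an estimated correlation). None of their members passed over all genes, and 4 fell, 3 rose and 0 passed when adjusted over the list alone. All 3 calls were lost without the mA16d#4 library in proliferation medium (adjusted p = 0.0974 each) or in differentiation medium (0.0512, 0.184 and 0.338), and the astrocyte call without the library labelled mA19d#7 (0.126). Pan-neuronal genes (median 0.18, adjusted p = 0.431), GABAergic interneuron genes (0.06, 0.965) and glutamatergic neuron genes (-0.05, 0.549) did not pass and held no gene past the test.

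The medians of the list responses differed between the Atrx-deleted lines. Cell cycle and DNA replication genes changed by a median of -1.61 and -1.24 in the control lines, by -1.28 in mA16d#4, and by -0.03 and -0.01 in mA19d#4 and mA19d#7. Interferon response genes changed by -1.06 and -1.07 in the control lines, and by 0.08, -0.44 and 0.24 in mA16d#4, mA19d#4 and mA19d#7. An exact permutation test over lines gave p = 0.3 for the first and 0.1 for the second list, the latter the smallest value the design allows. Adjusted over 29 lists these were 0.870 and 0.725. The values of mA19d#7 set the library labelled so against the proliferation library of that label.

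**Figure D4:**
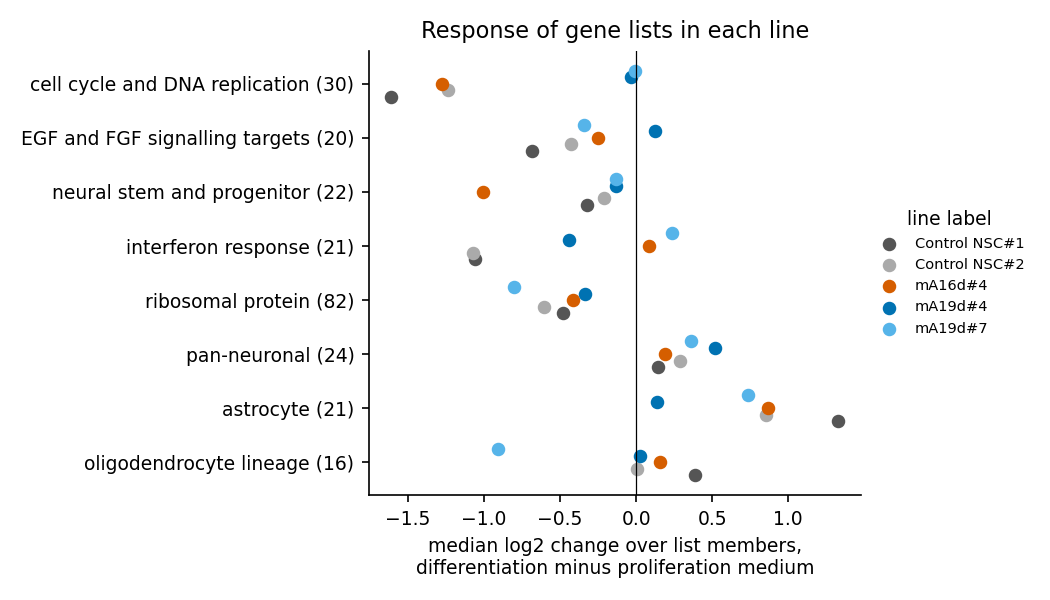
Median log2 change over the members of 8 gene lists (number tested in brackets) from proliferation to differentiation medium, with 1 point per line, coloured by line label. Cell cycle genes lie at -1.24 or below in both control lines and mA16d#4, and near 0 in the lines labelled mA19d#4 and mA19d#7.

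The test of whether the response to differentiation medium differed between Atrx-deleted and control lines called 1 gene. Tmem132b rose from 1.46 ± 1.38 to 96.2 ± 12.1 TPM (SD, n = 2) in the control lines and was at 0.269 ± 0.195 and 0.0777 ± 0.0608 TPM (SD, n = 3) in the Atrx-deleted lines. The difference of the log2 responses was -5.65 (SE 0.584, adjusted p = 0.0282). It stayed past 0.05 with 2 of the 10 libraries left out in turn, and reached 0.297 without the first control library in differentiation medium. The count was 3 without the library labelled mA19d#7, 0 with the cell line as a block, and 11 with the block without the line labelled mA19d#7. At an unadjusted p under 0.05, 1099 genes passed. Left out in turn, the first control library in proliferation medium, both control libraries in differentiation medium, the 3 Atrx-deleted proliferation libraries, and the mA16d#4 and mA19d#4 libraries in differentiation medium each gave 0. The numbers of genes called within the control and within the Atrx-deleted lines, 706 and 13, are therefore no evidence of different responses gene by gene.

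Among lists, the interaction was positive for genes of cell cycle and DNA replication (30, median 0.94, adjusted p = 9.34e-13) and for interferon response genes (21, median 1.05, adjusted p = 1.73e-06), and negative for astrocyte genes (21, median -0.56, adjusted p = 0.000366). With an estimated correlation the adjusted p was 0.718 for each. The median log2 level of the interferon response genes, relative to the median of their means over the 10 libraries, was 1.33 and 1.08 in the control proliferation libraries and between -0.53 and 0.60 in the other 8. Those 2 libraries enter each of the 3 comparisons in which that list passed. None of the members of the 3 lists passed over all genes, and 12 and 2 were positive and 3 negative when adjusted over the list alone. The astrocyte call was lost without the mA19d#4 library in differentiation medium (adjusted p = 0.138). Of the 706 genes called in the control lines, 661 (93.6%) changed in the same direction in the Atrx-deleted lines, with a median size of 0.56 against 1.63 in the control lines in which they were chosen. Called genes overlapped for 2 higher and 7 lower, where independent lists would share 0.039 and 0.282. These calls shared the estimate of spread per gene as well, so they were not independent. Across all 15660 genes, which are not independent replicates, the responses of control and Atrx-deleted lines correlated with Pearson's r 0.473.

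Genes of interest to the design that passed in none of the 5 comparisons were Daxx, Idh1, H3f3b, Sox2, Tubb3, Dcx, Map2, Gfap and Olig2. The stem cell factor gene Sox2 lay between 429 ± 10.5 and 536 ± 146 TPM in the 4 groups, and the neuronal microtubule gene Map2 between 506 ± 66.3 and 674 ± 282 TPM. Tubb3, a neuronal tubulin gene, was at 106 ± 5.90, 148 ± 14.4, 279 ± 101 and 220 ± 158 TPM in control proliferation, control differentiation, Atrx-deleted proliferation and Atrx-deleted differentiation. Dcx, which marks young neurons, was at 2.36 ± 0.116, 12.3 ± 7.68, 16.6 ± 14.8 and 29.7 ± 20.2 TPM in the same order. Idh1 was at 266 ± 8.72, 234 ± 11.9, 194 ± 69.0 and 153 ± 81.4 TPM, a value that does not separate the mouse gene from any transgene reads aligned to it. Olig2 lay at 1371 ± 20.2, 983 ± 48.1, 1023 ± 59.5 and 905 ± 481 TPM, and Daxx between 47.9 ± 18.3 and 65.8 ± 18.1 TPM. H3f3b, the second gene for H3.3, lay between 1098 and 1398 TPM and has near-identical copies, so its value is uncertain. Trp53 transcripts were present in these p53-null cells at 56.1 ± 4.97, 55.2 ± 0.974, 68.2 ± 1.99 and 114 ± 23.4 TPM, and the last group was above control differentiation (log2 1.01, SE 0.185, adjusted p = 0.0232).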

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

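The tests of a wrong label and of a response shared by other lines, for the library labelled mA19d#7, were chosen after the result was seen.

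A test of the difference in response to differentiation medium between Atrx-deleted and control lines called 1 gene and, with camera at a preset correlation, 3 lists. With an estimated correlation the camera adjusted p was 0.718 for each list, and with fry none passed. Tmem132b differed by log2 -5.65 (limma adjusted p = 0.0282), a rise in 2 of 2 control lines that was absent in 3 of 3 Atrx-deleted lines. With the cell line as a block no gene passed in limma (1099 had an unadjusted p under 0.05 without the block), and Tmem132b passed with 2 of the 10 libraries left out in turn. That block relied on the label mA19d#7, which is in doubt in differentiation medium. Without this line the block called 11 genes, Tmem132b among them, in a fit chosen after the results were seen. The median difference was -0.56 for astrocyte genes, 0.94 for cell cycle and DNA replication genes and 1.05 for interferon response genes. Over lines the exact permutation p was 0.3, 0.3 and 0.1. The line mA16d#4 lowered its cell cycle genes by a median of 1.28, near the control lines (1.61 and 1.24), and mA19d#4 by 0.03. The value of mA19d#7 rests on the library of doubtful label.

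The library labelled mA19d#7 in differentiation medium resembled mA16d#4. Of 28 genes that were silent or active in mA16d#4 alone in proliferation medium, 89.3% had the mA16d#4 state in that library, as many as in mA16d#4 itself in differentiation medium. A mixture is argued against, since genes silent in mA16d#4 were left at a median of 0.142% of their mA19d#7 level, and a shared response to the medium by the 14.3% of the 28 genes that reached this state in the nearest other line. A wrong line label may explain the pattern, with cells of mA16d#4 or a close relative under another name. Spearman's rho was 0.957 with mA16d#4 in proliferation medium and 0.938 with mA16d#4 in differentiation medium. The medium given by the label is therefore in doubt as well, and it was not tested. No partner for a swap was seen, but only 1 gene was private to mA19d#7 in proliferation medium. Its cells could therefore hardly be recognised in another library. Atrx was at 54.0 TPM in this library, as low as in other Atrx-deleted libraries, but neither DNA nor exons were examined. The Atrx-deleted group in differentiation medium may hold 2 independent lines and not 3. In proliferation medium mA19d#4 and mA19d#7 were the closest Atrx-deleted pair (Spearman's rho 0.976, against 0.953 and 0.954 with mA16d#4). Whether they are independent lines is not known either. The control libraries in that medium were closer still (Spearman's rho 0.983), and 0 genes were private to Control NSC#2. The independence of the control lines is therefore not known.

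Few genes passed for the medium in the Atrx-deleted lines. Over 500 genes chosen in 1 control line, the slope of the response was 0.526 or 0.799 in the other control line. It was at most 0.353 for an Atrx-deleted library. The control response was taken within the line, but that of each Atrx-deleted library against the mean of the 3 Atrx-deleted proliferation libraries. Apart from the doubted library, the ratio to the control slope was at most 0.468, under the 0.8 set for a like response. The baselines are unlike, so the slopes cannot settle whether the doubted library was the whole cause. Without that library the count rose from 13 to 348. A smaller response in the Atrx-deleted lines may be the reason, but the slopes of the control lines differed from each other too, and this stays open. The 6 libraries allow 10 splits, too few for a share under 0.05: the real split gave 13 genes, 2 splits gave as many with the real one included, and the highest other gave 480, in a split that parted both mA16d#4 libraries and the doubted library from the rest and points to a structure of the samples.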

How the results depend on the processing

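Tests of the deposited log2 values, with a weight per group, and with the line block without mA19d#7 were chosen after the results were seen. With each library left out in turn, the Atrx difference lay between -1.48 and -1.09 in proliferation medium, past 0.05 in 2 of 10 cases, and between -1.32 and -1.22 in differentiation medium, past 0.05 in 8 of 10. No named gene that passed changed direction in the settings run, but the balance of higher and lower calls between lines turned in some. In proliferation medium it was 30 to 43 with pseudocount 5 and 22 to 26 without trend (41 to 31 as reported). In differentiation medium it was 196 to 243 with pseudocount 5 and 133 to 178 with no filter (243 to 209 as reported). In proliferation medium 72 genes became 37 (7 higher) with no filter, 39 (29 higher, 37 shared) on the deposited log2 values, 672 with group weights and 0 to 249 with a library or line left out. In differentiation medium 452 became 2 with the compared groups fitted alone and 1 to 935 with a library or line left out. For the medium in control lines 706 became 2080 with the compared groups alone, 2984 with group weights, 1848 with the line as a block without mA19d#7, and 0 to 1447 with a library or line left out. In Atrx-deleted lines 13 became 7 with pseudocount 5, 2 with no filter, 0 without trend, 0 with the compared groups alone, 6 with the line as a block, 1 with group weights, 335 with the block without mA19d#7, and 0 to 348 with a library or line left out. The interaction count of 1 became 0 with pseudocount 0.1, 2 with pseudocount 5, 30 with no filter, 0 with a filter of TPM 5, 2 without trend, 0 with the block, 0 on the deposited log2 values, 6 with group weights, 11 with the block without mA19d#7, and 0 to 3 with a library or line left out. The lists past camera, 27, became 0 with an estimated correlation and 4 with fry. For these changes the cause was not tested, except that fewer libraries leave fewer degrees of freedom. A lone library left in a group was taken to vary like the other groups. Depth is unknown, so its limit cannot be given. Of the named genes that passed, 0 of 24, 6 of 53, 2 of 51, 0 of 12 and 0 of 1 passed with each library left out in turn, in the order of the comparisons above. Robust estimation, median-of-ratios factors and the line as a random block left the 5 counts within 1.5 times.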

Other observations

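The tests of X-linked genes and of neighbouring genes, and the threshold of 0.4 in the scan of windows, were chosen after results were seen.

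The distal end of chromosome 2 was higher in 6 of 6 Atrx-deleted libraries, with a median log2 difference of 0.740 in the last 5 Mb. Of 14501 windows of 50 genes, 80 were beyond 0.4 in all 6 libraries, and all 80 lay on chromosome 2. Smaller shifts ran over other whole chromosomes. The chromosome median was lower in 6 of 6 libraries on chromosome 16 (-0.394 to -0.243), chromosome 7 (-0.407 to -0.0824) and chromosome 18 (-0.365 to -0.0308), and higher in 6 of 6 on chromosome 8 (0.12 to 0.268) and chromosome 1 (0.0702 to 0.228), among others. On the X chromosome it was lower in 5 of 6. These libraries share their lines and the control mean of each medium, so they are not 6 independent observations, and no test was run on the chromosome medians. The last 5 Mb of the other chromosomes had a median of -0.0432, which argues against a rise of chromosome ends in general. An altered copy number may explain the step, either a gain in the Atrx-deleted lines or a loss in the control lines, and DNA was not analysed here.

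Among called genes the lowest odds ratio over the media was 1.31 for genes on the X chromosome (exact p = 0.238, in differentiation medium; 3.02 in proliferation medium, exact p = 0.0122) and 1.55 for genes within 5 Mb of a distal chromosome end (exact p = 0.0158, in differentiation medium; 2.76 in proliferation medium, exact p = 0.00623). Of the X-linked calls, 18 of 20 were lower in differentiation medium and 5 of 7 in proliferation medium, the deleted gene Atrx among them in both. Without chromosome 19 the distal odds ratio in proliferation medium was 2.22 (exact p = 0.0571). Without chromosome 2 the distal odds ratio in differentiation medium was 1.14 (exact p = 0.506). Neighbouring genes called in the same direction formed 0 pairs in proliferation medium, where random placement gave a median of 0, and 22 in differentiation medium, where it gave a median of 6 (permutation p = 1e-04, the smallest that 10000 placements give). Aurka with Cstf1, Zbtb46 with Tpd52l2, Tpd52l2 with Dnajc5 and Znf512b with Prpf6 lay in the raised segment of chromosome 2. The pairs among 6430706D22Rik, A730008H23Rik and Hjurp had overlapping spans. Random placement takes account of neither, so this p-value does not show that called genes cluster elsewhere.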
